A study of Mus musculus with 12 samples.

How the data were processed

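RNA-seq was done on brown adipose tissue of 4 groups of mice, WT_PBS, WT_CL, ERRKO_PBS and ERRKO_CL, with 3 libraries each and group and replicate taken from the labels. Injections were given intraperitoneally at ZT 4, per the labels' protocols, and libraries were made from 1 µg of total RNA with a TruSeq total RNA kit. bcl2fastq 2.16.0.10, cutadapt, STAR 2.3.0 and edgeR are named in the submitters' processing notes, with mouse builds mm9 and mm10 and no role for either. The counting tool, annotation and use of strand are not given in the sources used here, so values of genes that overlap others, such as Cpt1b with 81.4% of its exon bases and Adrb3 with 24.9%, or that have close paralogs, such as Acaa1b, Kng2, Ly6c2, Akr1cl and the haemoglobin genes, are uncertain.

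The main table gives RPKM values deposited by the authors for 24452 genes, of which 6296 are at 0 in every library. RPKM scales reads to gene length and to a library total, which the authors do not state. The second deposited table gives 12380 genes, all also in the RPKM table, as a linear signal despite a name that says log CPM. Within each library every value of that signal is a whole multiple of a step, and 100% of values came out whole within a tolerance of 0.01, so reads were recovered by dividing by the step. Each gene of this table has at least 40 recovered reads in some library. Beside the sample columns 9 stray cells were not used. Totals behind the RPKM were estimated from 140 single-exon genes, whose annotated length converts RPKM and reads to a total. Depth limits precision for low genes, where values rest on few reads.

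The test set before the data were examined was limma 3.58.1 in R 4.3.3 (empirical Bayes with trend) on log2 of deposited RPKM plus 0.5, for 12249 genes with a mean RPKM of at least 0.5, with all 12 libraries in a single fit of 4 group means and 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 5 comparisons, at a threshold of 0.05. The values named in the text come from the same fit after median-of-ratios scaling of the libraries, an alternative listed before the data were examined and chosen as the reporting scale after the shift between genotypes was seen. Log2 changes on this scale, with 0.5 added, understate the change of low genes. A count test, edgeR 4.0.16 quasi-likelihood, was run on the recovered reads of 12380 genes. It called 4305 genes for ERRKO_PBS against WT_PBS, 5083 for ERRKO_CL against WT_CL, 3633 for WT_CL against WT_PBS, 1218 for ERRKO_CL against ERRKO_PBS and 412 for the interaction.

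Gene lists, 32 in number, were fixed before the data were examined, and 30 with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The camera test compares a list with the other genes, while fry asks whether the members of a list changed at all. A call by fry therefore does not replace a lost camera call. Named genes were the 5 largest rises and 5 largest falls among called genes with a mean RPKM of at least 1 and complete separation of the groups (without separation for the interaction), up to 4 members of each described list with the smallest p, and Esrra, Esrrg, Esrrb, Ucp1, Ppargc1a, Dio2, Cidea, Elovl3 and Fgf21 always. A gene named for one comparison may be given for others. Esrrb and Fgf21 did not reach the filter. Coordinates are 1-based and come from GENCODE M21 on GRCm38, not from the files.

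Alternatives were other pseudocounts of 0.1 and 1, no filter and a mean RPKM of at least 2, quantile normalization, robust and untrended fits, library weights, only the groups compared, the second deposited table, the count test, a replicate block and each library left out in turn. After seeing the data, a fit without ERRKO_PBS replicate 3 and ERRKO_CL replicate 3, a fit with muscle transcript level as a covariate, and all settings on the median-ratio scale were added. The procedure on the median-ratio scale was tested on simulated data for ERRKO_CL against ERRKO_PBS with 11874 genes: 28.8% of genes changed 1.5-fold were recovered, 77.3% at 2-fold and 98.4% at 4-fold, and 8 of 141 calls were false. Gene means in the simulation were the same in all groups, apart from the genes changed in ERRKO_CL. Genes varied independently, without a shared muscle component or a genotype effect, so these rates need not hold for the real libraries.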

Results

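Total RNA from brown adipose tissue of 12 male C57BL/6J mouse samples was sequenced in 4 groups of 3 libraries. Brown adipose tissue is the fat depot that produces heat by uncoupled respiration. WT samples came from floxed littermates without Cre, and ERRKO samples from mice in which adiponectin-Cre deleted ERRα and ERRγ, nuclear receptors that drive genes of oxidative metabolism, in adipocytes. Each genotype received PBS or CL316,243, an agonist of the β3-adrenergic receptor, at 1 mg/kg daily for 10 days, in mice 12 weeks of age kept at 30 °C. Tissue was taken 24 h after the last dose. The recovered reads per library ranged from 8478310 to 9727167 in WT_PBS, 8979123 to 9559239 in WT_CL, 12822176 to 13263567 in ERRKO_PBS and 12468001 to 12954186 in ERRKO_CL. The labels do not say that the libraries of a group are separate animals, so p-values measure the spread between these samples, and no pair of libraries held identical values.

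On the deposited RPKM scale the typical gene of 12249 tested was higher in ERRKO than in WT libraries, by 0.53 (log2) under PBS and 0.63 under CL316,243. The corresponding shift was -0.26 for CL316,243 in WT, -0.16 in ERRKO and 0.09 for the interaction. Gene and list values are therefore given on a median-ratio scale, which sets the typical gene to no change, and total counts and the counts for most lists described are given on both scales. Levels are scaled RPKM (mean ± SD, n = 3 per group). Changes are log2 of scaled RPKM plus 0.5 (± SE) with limma p-values adjusted by the Benjamini-Hochberg method.

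The deleted genes were examined first. Esrra, which encodes ERRα (chromosome 19, 6910977 to 6921813, minus strand), was at 43.6 ± 2.85 in WT_PBS, 79.5 ± 3.77 in WT_CL, 7.60 ± 2.04 in ERRKO_PBS and 7.96 ± 1.07 in ERRKO_CL. All 6 ERRKO libraries lay below all 6 WT libraries, between 5.25 and 8.89 against 41.6 to 83.3. Esrrg, which encodes ERRγ (chromosome 1, 187608791 to 188214885, plus strand), was at 6.88 ± 2.14, 6.93 ± 1.26, 3.53 ± 1.21 and 7.06 ± 0.945 in the same order. Esrrg was lower in ERRKO_PBS than in WT_PBS (-0.87 ± 0.25, adjusted p = 0.018) but level with WT under CL316,243 (0.03 ± 0.25, adjusted p = 0.94), and the interaction of 0.90 ± 0.35 did not pass (adjusted p = 0.197). With CL316,243 Esrrg rose in ERRKO (0.95 ± 0.25, adjusted p = 0.034), a call lost on the deposited scale (0.77, adjusted p = 0.070) and without ERRKO_PBS replicate 1 or 2 or any ERRKO_CL replicate (adjusted p = 0.087, 0.104, 0.068, 0.081 and 0.108). On the deposited scale Esrrg was higher in ERRKO_CL than in WT_CL (0.69, adjusted p = 0.034). The Esrrg call under PBS was lost on the deposited scale (-0.34, adjusted p = 0.274) and without WT_PBS replicate 1, WT_PBS replicate 2 or ERRKO_PBS replicate 2 (adjusted p = 0.070, 0.069 and 0.071). A value for the whole gene can include exons outside the deleted part, which the labels do not name. Cells of the tissue other than adipocytes also keep the gene. How far either accounts for the Esrrg left in ERRKO was not tested, so the check of the genotype labels rests on Esrra. Esrrb, the remaining family member, lay below the filter on low values in this tissue.

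**Figure D1:**
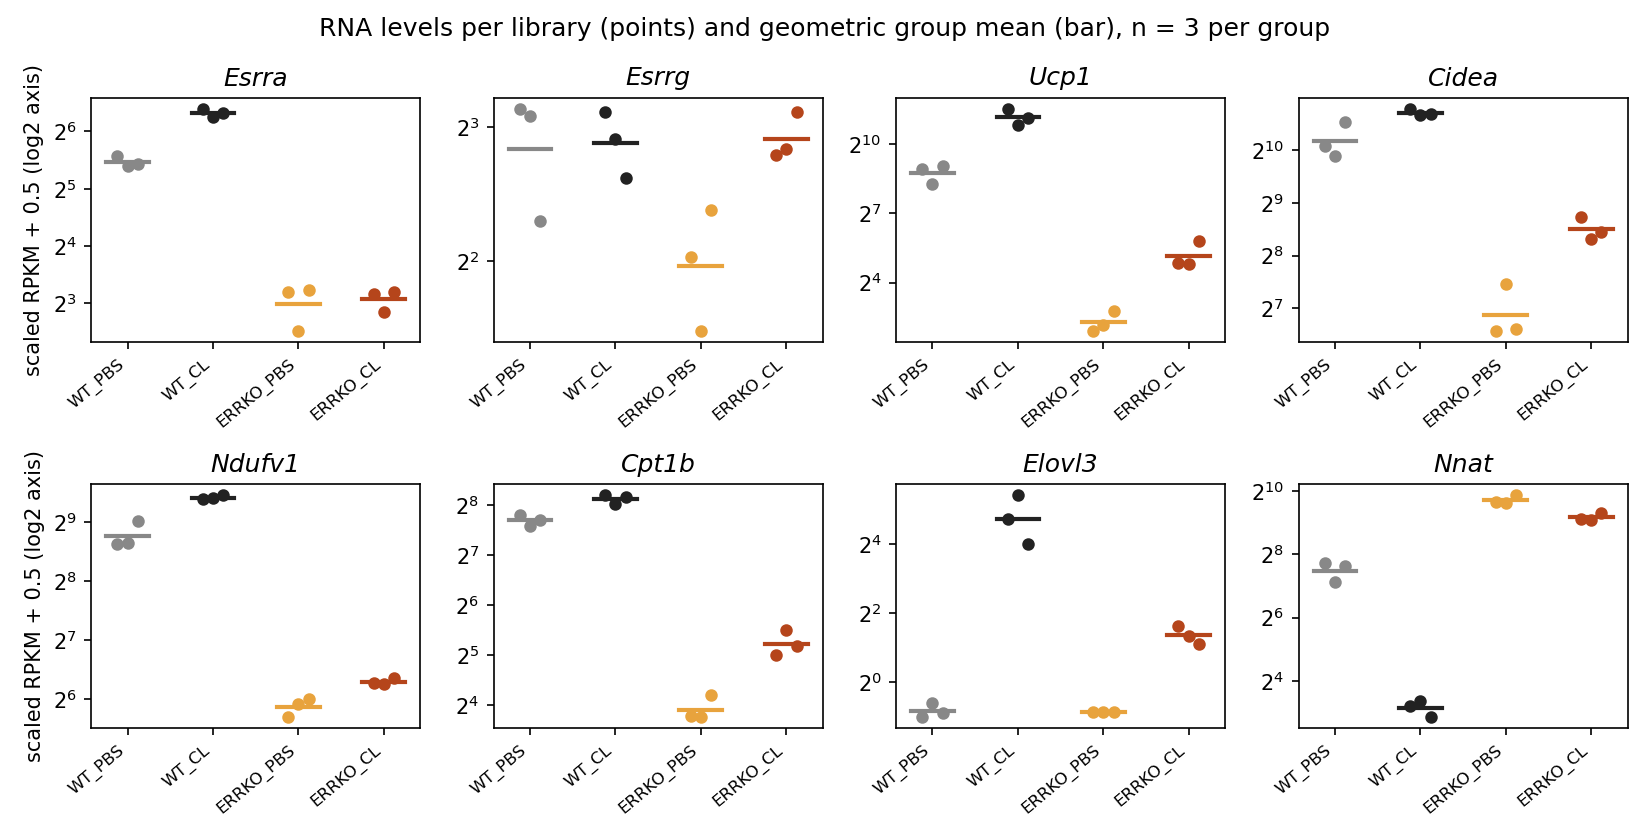
Scaled RPKM plus 0.5 of 8 genes (log2 axis) in each library of the 4 groups, with points for libraries and bars for geometric means of 3 libraries. Esrra is low in all 6 ERRKO libraries, and arithmetic means of scaled RPKM are 446 in WT_PBS and 4.52 in ERRKO_PBS for Ucp1 and 27.6 in WT_CL and 2.09 in ERRKO_CL for Elovl3.

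The comparison of ERRKO_PBS with WT_PBS asked what the deletion changed without agonist. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452, plus strand), fell from 446 ± 117 to 4.52 ± 1.64 (-6.49 ± 0.31, adjusted p = 2.9e-08). Most nuclear genes of the respiratory chain fell. Of 36 measured complex I genes all 36 fell (median -2.02), among them Ndufv1 (-2.89 ± 0.12), Ndufa10 (-2.26 ± 0.12) and Ndufs1 (-2.25 ± 0.12). All 14 genes of complexes II and III fell (median -2.33), led by the electron carrier Cycs at -3.54 ± 0.15, as did 13 of 14 genes of complex IV (median -2.23) with Cox5a at -2.96 ± 0.16. Among 16 ATP synthase genes 13 fell and 1 rose (median -1.92), with Atp5b at -2.58 ± 0.14.

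Transcripts of fuel oxidation genes were also mostly lower. Of 25 genes of the TCA cycle and pyruvate oxidation 24 fell and 1 rose (median -2.09), including Idh3b (-3.16 ± 0.11) and Ogdh (-2.63 ± 0.09). Of 26 fatty acid oxidation genes 20 fell, 1 rose and 5 did not pass (median -1.39), among them the acyl-CoA synthetase Slc27a2 (41.8 ± 6.50 to 0.701 ± 0.412, -5.18 ± 0.20) and Cpt1b (-3.78 ± 0.14), the muscle-type carnitine palmitoyltransferase, 81.4% of whose exon bases overlap another annotated gene. Glucose uptake and glycolysis genes also fell in 14 of 22 cases, with 2 that rose (median -1.04), including Ldhb (-3.74 ± 0.16) and Pgk1 (-2.43 ± 0.13). Of 72 mitochondrial ribosome genes 63 fell and 9 did not pass (median -0.80), with Mrps36 at -2.68 ± 0.13. Of 14 mitochondrial chaperones and proteases 10 fell (median -0.75), with Afg3l2 at -2.02 ± 0.08. Of 20 genes of mitochondrial biogenesis and DNA maintenance 11 fell (median -0.45), with the transcription factor Tfb2m at -1.30 ± 0.08. Adjusted over the list alone, 36 genes of complex I, 25 of the TCA list, 21 of fatty acid oxidation, 16 of glycolysis and 65 of the mitochondrial ribosome passed in either direction. With deposited scaling complex I had 36 lower, complexes II and III 14, complex IV 13 with 1 higher, ATP synthase 11 with 2 higher, the TCA list 23 with 1 higher and fatty acid oxidation 18 with 4 higher. Smaller changes depended on the scale: there the mitochondrial ribosome had 32 lower and 7 higher (median -0.22), chaperones 5 lower and 5 higher (median -0.16), glycolysis 10 lower and 6 higher (median -0.45) and biogenesis 5 lower and 7 higher, where the median turned to 0.12.

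Of 25 thermogenic and brown adipocyte genes 16 fell and 1 rose under PBS (median -1.63), and 17 passed adjusted over the list alone. Cidea, a lipid droplet protein of brown fat, fell from 1175 ± 276 to 122 ± 45.7 (-3.29 ± 0.23), and the deiodinase Dio2 from 2.02 ± 1.22 to 0.245 ± 0.0459 (-1.65 ± 0.36, adjusted p = 3.8e-03). Ppargc1a, the coactivator of mitochondrial genes, did not pass at 6.95 ± 3.63 in ERRKO_PBS against 4.90 ± 0.501 in WT_PBS (0.35 ± 0.31, adjusted p = 0.41) but passed on the deposited scale (0.90, adjusted p = 0.024), and Elovl3 was near 0 in both groups (-0.03 ± 0.28). The largest falls also took in Kng2, which encodes a kininogen and has close paralogs (-6.65 ± 0.17), Fabp3, a fatty acid carrier of muscle and brown fat (-6.05 ± 0.63), and Cox7a1, the muscle-type subunit of complex IV (-5.17 ± 0.45). Among the ERRKO_PBS libraries Fabp3 and Cox7a1 were both highest in replicate 3, at 57.6 and 38.5, where muscle creatine kinase Ckm was also highest at 389. This rests on that replicate. Ckm was at 11.1 in replicate 2 and 46.7 in replicate 1, while Cox7a1 was at 9.26 and 8.73 and Fabp3 at 6.65 and 7.63.

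Of 12 adipocyte genes typical of white fat 8 were measured. Under PBS 7 of these 8 rose and none fell (median 2.01), and 7 passed adjusted over the list alone. They included resistin Retn (2.99 ± 0.33), Nnat (2.23 ± 0.17) and Ccdc80 (2.63 ± 0.33). Pan-adipocyte genes rose in 6 of 12 cases, among them the lipid droplet genes Plin1 (0.79 ± 0.13) and Cidec (0.85 ± 0.14). The largest rises were those of the potassium channel Kcnk2 (0.416 ± 0.136 to 12.7 ± 1.06, 3.86 ± 0.15), the sulfotransferase Chst1 (3.61 ± 0.19), Fam83a (3.59 ± 0.42), the β3-adrenergic receptor gene Adrb3 (21.1 ± 3.51 to 217 ± 34.4, 3.33 ± 0.27) and Psat1 of serine synthesis (3.32 ± 0.28). Interferon response genes rose in 10 of 21 cases (median 0.56), and in 12 adjusted over the list alone, including Ifit3 (1.46 ± 0.30) and Irf7 (1.12 ± 0.25). With deposited scaling 8115 of all 12249 tested genes were called higher. It gave 15 lower and 6 higher thermogenic genes, 8 higher white adipocyte genes, 11 higher pan-adipocyte genes and 21 higher interferon response genes. Skeletal muscle genes had a median of 3.21 with 0 of 18 members passing, and spread widely within each group, with 16 members passing on the deposited scale, and with Ckm from 0.0516 to 37.9 in WT_PBS and 11.1 to 389 in ERRKO_PBS. The direction of the list test for muscle turned on the deposited scale (adjusted p = 0.767).

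In total 4189 genes passed between ERRKO_PBS and WT_PBS (limma, adjusted p under 0.05), 1912 higher and 2277 lower in ERRKO, of which 401 were at least 2-fold higher and 624 at least 2-fold lower. On the deposited scale 8877 passed, 8115 higher and 762 lower. The list test (camera) called 18 of 30 lists, and with an estimated correlation it kept 2, the thermogenic list (adjusted p = 4.3e-07, and adjusted p = 0.047 with an estimated correlation) and the white adipocyte list (1.3e-05, and 0.047). The mitochondrial lists were lost: adjusted p with an estimated correlation was 0.163 for complex I, 0.145 for complexes II and III, 0.163 for complex IV, 0.260 for ATP synthase, 0.145 for the TCA cycle, 0.145 for fatty acid oxidation, 0.058 for biogenesis, 0.260 for the mitochondrial ribosome and 0.260 for chaperones. It was 0.163 for glycolysis and 0.311 for pan-adipocyte genes. It was 0.311 for the interferon response and 0.649 for skeletal muscle. The other list test, fry, asks whether members changed at all, not whether they changed more than other genes. It called the mitochondrial lists, with adjusted p of 3.3e-06 for complex I, 6.2e-07 for complexes II and III and 2.9e-06 for complex IV. It gave 1.1e-05 for ATP synthase, 3.0e-07 for the TCA cycle, 1.8e-06 for fatty acid oxidation and 1.4e-04 for the mitochondrial ribosome. Skeletal muscle was not called by fry (0.146). On the deposited scale 7 of 14 camera calls held with an estimated correlation.

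With CL316,243 in both genotypes, ERRKO_CL was compared with WT_CL. Ucp1 was at 36.8 ± 15.4 against 2359 ± 570 (-6.03 ± 0.31, adjusted p = 3.1e-08), Cidea at 365 ± 56.5 against 1686 ± 69.7 (-2.22 ± 0.23) and Dio2 at 2.83 ± 1.23 against 9.46 ± 3.15 (-1.61 ± 0.36). All 36 complex I genes were lower (median -2.26), as were all 14 genes of complexes II and III (-2.73), 13 of 14 of complex IV (-2.46), 14 of 16 of ATP synthase (-2.17) and 24 of 25 TCA genes with 1 higher (-2.44). Fatty acid oxidation genes were lower in 22 of 26 cases and higher in 1 (-1.35), and mitochondrial ribosome genes lower in 68 of 72 (-1.06). Adjusted over the list alone, the same counts held for complex I, complexes II and III, complex IV and the TCA list at 36, 14, 13 and 25 passing. With deposited scaling 34 complex I genes were lower, 14 of complexes II and III, 13 of complex IV with 1 higher, 11 of ATP synthase with 2 higher, 24 of the TCA list with 1 higher, 18 of fatty acid oxidation with 4 higher, and 41 of the mitochondrial ribosome with 8 higher (median -0.36).

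De novo lipogenesis genes were lower in 9 of 18 cases (median -1.13), and in 12 adjusted over the list alone, including the fatty acid elongases Elovl3 (2.09 ± 0.465 against 27.6 ± 13.3, -3.34 ± 0.28) and Elovl6 (-3.25 ± 0.34) and the ATP citrate lyase gene Acly (-2.85 ± 0.46). Cholesterol synthesis genes were lower in 8 of 18 (median -0.40) and glycolysis genes in 16 of 22, with 1 higher (median -1.24). Cell cycle genes were lower in 15 of 25 cases (median -0.60), among them Mki67 (-1.20 ± 0.22) and Top2a (-1.15 ± 0.22). White adipocyte genes were higher in 6 of 8 (median 2.34), led by Nnat (575 ± 50.8 against 8.47 ± 1.57, 6.02 ± 0.17) and Retn (3.71 ± 0.33), and extracellular matrix genes in 18 of 24 (median 0.61), including Col6a2 (1.00 ± 0.16) and Col5a1 (0.95 ± 0.16). Other large differences were higher Phgdh of serine synthesis (3.88 ± 0.22), Fam83a (3.88 ± 0.42) and Sncg (3.81 ± 0.29), and lower Cox7a1 (-5.52 ± 0.45), Kng2 (-5.13 ± 0.17), the acyl-CoA thioesterase Acot11 (-4.90 ± 0.32) and Fam131c (-4.53 ± 0.21), which was near 0 outside WT_CL. With deposited scaling 8640 of all 12249 tested genes were called higher. Deposited scaling gave 5 lower and 2 higher lipogenesis genes (median -0.43), 13 lower and 4 higher glycolysis genes, 7 lower and 5 higher cell cycle genes, 8 higher white adipocyte genes and 22 higher extracellular matrix genes. It turned the median of cholesterol synthesis to 0.20, with 5 lower and 4 higher. Skeletal muscle genes had a median of 2.91 with 0 of 18 members passing, or 10 on the deposited scale. Their list call (adjusted p = 0.023, and adjusted p = 0.725 with an estimated correlation) was lost on the deposited scale (adjusted p = 0.336).

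Between ERRKO_CL and WT_CL 5073 genes passed, 2433 higher and 2640 lower in ERRKO, with 461 and 781 at 2-fold or more. The deposited scale gave 9451, 8640 higher and 811 lower. Of 30 lists 18 were called, and 3 kept the call with an estimated correlation: thermogenic (lower in 18 of 25 and higher in 2, or 14 and 4 on the deposited scale, adjusted p = 0.029 with an estimated correlation), mitochondrial biogenesis (lower in 12 of 20, 0.029, but 8 lower and 8 higher with a median of 0.11 on the deposited scale) and white adipocyte (0.029). Adjusted p with an estimated correlation was 0.157 for complex I, complexes II and III, complex IV and fatty acid oxidation, 0.213 for ATP synthase and the mitochondrial ribosome, 0.140 for the TCA cycle and glycolysis, 0.435 for lipogenesis, cholesterol synthesis and the cell cycle, and 0.264 for extracellular matrix. On the deposited scale 8 of 17 camera calls held with an estimated correlation. By fry the adjusted p was 1.3e-06 for complex I, 1.5e-07 for complexes II and III and 7.6e-08 for the TCA cycle. Skeletal muscle was not called by fry (0.247). Across genes, which are not independent replicates, the genotype effects under PBS and under CL316,243, which share no library, correlated at r = 0.816. Of the genes called, 1294 were higher in both against 380 for independent lists and 1717 lower in both against 491, while 13 and 27 were called in opposite directions.

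**Figure D2:**
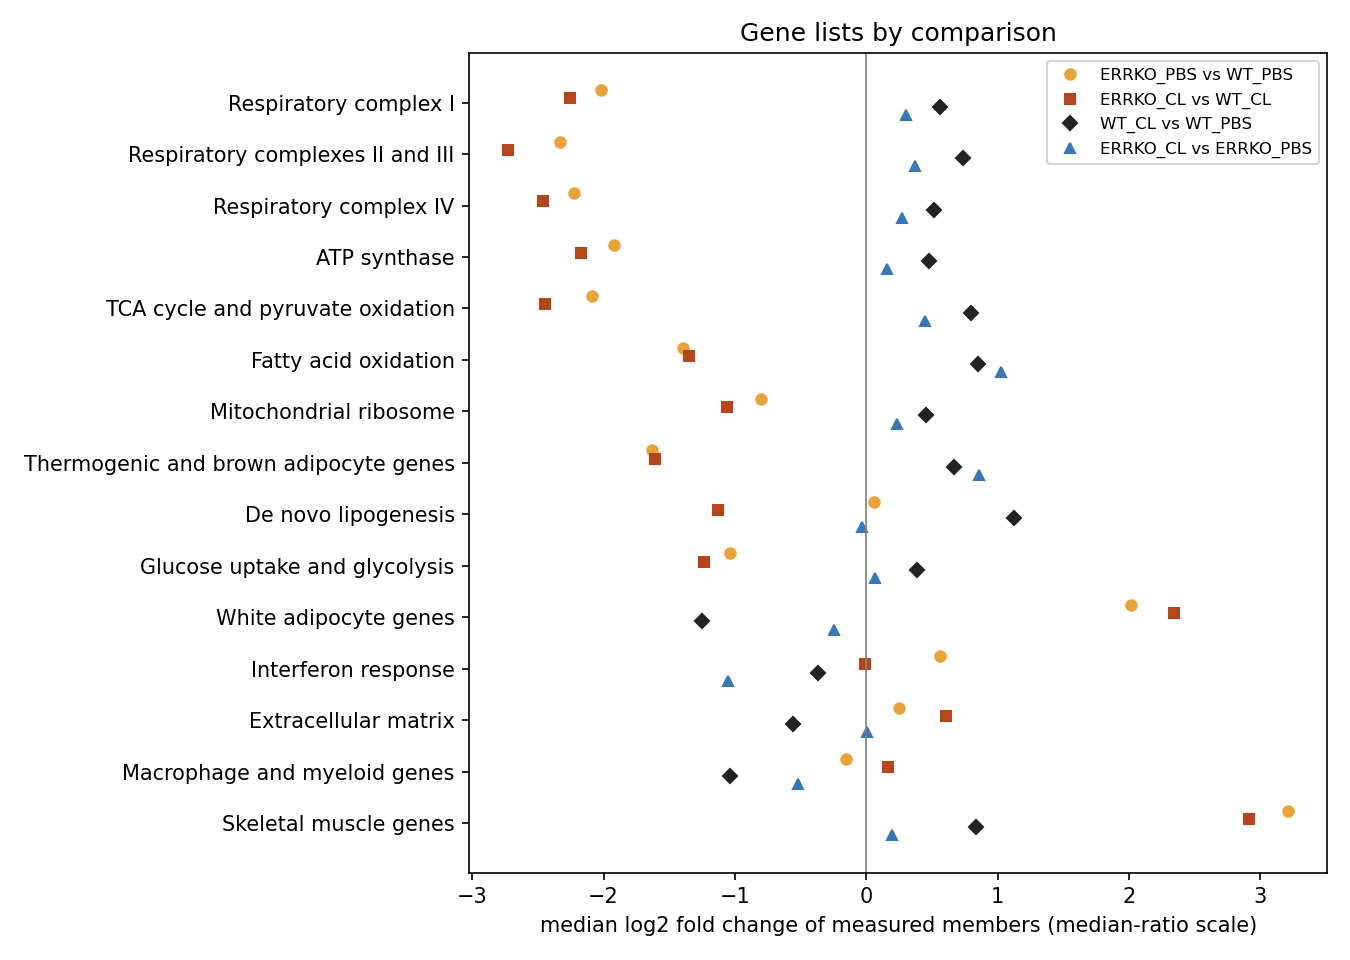
Median log2 fold change of the measured members of 15 gene lists (vertical axis) in each of 4 comparisons, on the median-ratio scale. Respiratory chain and TCA lists lie between -1.92 and -2.73 in both genotype comparisons, and white adipocyte genes at 2.01 and 2.34.

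The response of WT tissue to CL316,243 was the next comparison. Elovl3, a fatty acid elongase induced in active brown fat (chromosome 19, 46131897 to 46135694, plus strand), rose from 0.0645 ± 0.0810 to 27.6 ± 13.3 (5.54 ± 0.28, adjusted p = 2.7e-07). Ucp1 rose from 446 ± 117 to 2359 ± 570 (2.41 ± 0.31, adjusted p = 1.8e-04) and Dio2 from 2.02 ± 1.22 to 9.46 ± 3.15 (2.05 ± 0.36), while Cidea at 0.55 ± 0.23 (adjusted p = 0.099) and Ppargc1a at 0.65 ± 0.31 (adjusted p = 0.131) did not pass. The Cidea rise passed without WT_PBS replicate 3 (0.73, adjusted p = 0.036) and without ERRKO_PBS replicate 2 (0.55, adjusted p = 0.033). Esrra itself rose by 0.86 ± 0.16 (adjusted p = 2.4e-03). The other large rises were Aspg (5.12 ± 0.26), Fam131c (4.47 ± 0.21), the peroxisomal thiolase Acaa1b (4.07 ± 0.27), which has the close paralog Acaa1a, and Fndc5 (3.97 ± 0.41). The largest falls were Nnat (181 ± 37.5 to 8.47 ± 1.57, -4.33 ± 0.17), Tusc3 (-3.77 ± 0.11), clusterin Clu (-3.72 ± 0.10), Akr1cl (-3.62 ± 0.30) and 8430408G22Rik (-3.38 ± 0.57).

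In WT the agonist raised 12 of 18 de novo lipogenesis genes with none that fell (median 1.12), and 15 adjusted over the list alone, including Elovl6 (2.46 ± 0.34), Fasn (2.71 ± 0.50) and Slc25a1 (1.85 ± 0.38). Fasn varied from 355 to 1328 among the WT_CL libraries. It raised 23 of 25 TCA genes (median 0.80), 18 of 26 fatty acid oxidation genes with 1 that fell (median 0.85), 24 of 36 complex I genes (median 0.56), 13 of 14 genes of complexes II and III (median 0.74) and 49 of 72 mitochondrial ribosome genes (median 0.46). Examples were Acsl5 (2.67 ± 0.19), Slc25a20 (1.56 ± 0.09), Dlst (1.06 ± 0.10) and Uqcrc2 (1.05 ± 0.12). Thermogenic genes rose in 14 of 25 and fell in 2 (median 0.67), triglyceride genes rose in 14 of 23 and fell in 3 (median 0.68). Glycolysis genes rose in 10 of 22 (median 0.39) and cholesterol synthesis genes in 7 of 18 (median 0.32). Macrophage and myeloid genes fell in 14 of 22 (median -1.04), and in 19 adjusted over the list alone, with Csf1r at -1.26 ± 0.17 and C1qb at -1.03 ± 0.16. Interferon response genes fell in 6 of 21 (median -0.37, adjusted p = 0.434 with an estimated correlation), and in 13 on the deposited scale. Extracellular matrix genes fell in 12 of 24 (median -0.55), and white adipocyte genes fell in 5 of 8 and rose in 2 (median -1.25), including leptin Lep (-1.54 ± 0.18), a list call lost on the deposited scale (adjusted p = 0.157). Deposited scaling gave fewer rises: 9 lipogenesis genes with 1 that fell, 19 TCA genes with 1 that fell, 15 of fatty acid oxidation with 1 that fell, 12 of complex I, 11 of complexes II and III and 21 of the mitochondrial ribosome with 3 that fell. It gave 10 rises and 2 falls of thermogenic genes, 9 and 6 of triglyceride genes, 5 and 1 of glycolysis and 4 and 2 of cholesterol synthesis. Macrophage genes fell in 20 cases there, extracellular matrix genes in 19 and white adipocyte genes in 5 with 1 rise. On that scale 4671 of all 12249 tested genes were called lower.

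For CL316,243 in WT 3717 genes passed, 2218 higher and 1499 lower, with 322 and 251 at 2-fold or more. The deposited scale gave 5553, 882 higher and 4671 lower. All 22 list calls were lost with an estimated correlation: the adjusted p with an estimated correlation was 0.345 for lipogenesis, 0.286 for the TCA cycle, 0.272 for fatty acid oxidation, 0.393 for complex I, 0.342 for complexes II and III, 0.363 for the mitochondrial ribosome, 0.063 for thermogenic genes, 0.295 for triglyceride genes, 0.342 for glycolysis, 0.520 for cholesterol synthesis, 0.260 for macrophage genes, 0.345 for extracellular matrix and 0.260 for white adipocyte genes. By fry the adjusted p was 1.9e-04 for the TCA cycle, 8.4e-05 for fatty acid oxidation, 0.012 for complex I and 0.0039 for lipogenesis. Neither the interferon response (0.082) nor endothelial genes (0.146) were called by fry.

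In ERRKO tissue the agonist was compared with PBS in the same way. Slc27a2 rose from 0.701 ± 0.412 to 13.7 ± 1.07 (3.61 ± 0.20, adjusted p = 6.2e-06), the mitochondrial carrier Slc25a34 from 0.731 ± 0.570 to 11.5 ± 5.78 (3.27 ± 0.56) and Ucp1 from 4.52 ± 1.64 to 36.8 ± 15.4 (2.87 ± 0.31, adjusted p = 4.2e-04). Cidea rose by 1.62 ± 0.23, Dio2 by 2.08 ± 0.36 and Elovl3 by 2.22 ± 0.28, to 2.09 ± 0.465. Adtrp (2.36 ± 0.30) and Cyp2e1 (2.45 ± 0.62, adjusted p = 0.027) were the other largest rises. The largest falls were Prr32 (-2.64 ± 0.34), Ly6c2 (-2.26 ± 0.30), the chemokine Ccl7 (-2.04 ± 0.37), Ppp1r1b (-2.03 ± 0.40) and Emp1 (-1.90 ± 0.28).

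Of 26 fatty acid oxidation genes 20 rose and none fell in ERRKO (median 2.03-fold), and 21 adjusted over the list alone, among them Slc25a20 (1.61 ± 0.09), Etfdh (1.36 ± 0.12) and Acadvl (1.27 ± 0.14). TCA genes rose in 15 of 25 (median 0.45), and thermogenic genes rose in 14 of 25 and fell in 1 (median 0.86). Complex I genes rose in 3 of 36 (median 0.30) and mitochondrial ribosome genes in 7 of 72 (median 0.24), while of 18 lipogenesis genes 1 rose, Elovl3. Interferon response genes fell in 19 of 21 cases (median -1.05), and in 20 adjusted over the list alone, with Usp18 at -1.58 ± 0.25 and Oasl2 at -1.23 ± 0.17. Macrophage genes fell in 7 of 22 and rose in 1 (median -0.52), with C1qa at -1.21 ± 0.23 and the rise that of S100a8 (1.97 ± 0.33). With deposited scaling 18 fatty acid oxidation genes rose and 1 fell, 6 TCA genes rose, 13 thermogenic genes rose and 1 fell, 1 mitochondrial ribosome gene rose, and of complex I none rose and 1 fell. Interferon response genes fell in 20 cases there and macrophage genes in 11 with 1 rise. The 2 richest libraries in muscle transcripts were among those compared here, with Ckm at 389 in ERRKO_PBS replicate 3 and 213 in ERRKO_CL replicate 3.

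For CL316,243 in ERRKO 1293 genes passed, 859 higher and 434 lower, with 105 and 95 at 2-fold or more, and on the deposited scale 2068, of which 396 were higher and 1672 lower. Without those 2 libraries 472 genes passed, the Dio2 (1.84, adjusted p = 0.051), Ccl7 (-1.96, adjusted p = 0.058) and C1qa (-1.05, adjusted p = 0.072) calls were lost, and the counts ranged from 533 without ERRKO_PBS replicate 1 to 1708 across single libraries left out. Of 17 lists called, the thermogenic list kept its call with an estimated correlation (adjusted p = 0.032 with an estimated correlation), and the others did not, at 0.099 for fatty acid oxidation, 0.099 for the interferon response, 0.267 for the TCA cycle, 0.267 for macrophage genes, 0.633 for complex I and 0.633 for the mitochondrial ribosome. By fry the adjusted p was 8.1e-05 for fatty acid oxidation, 0.0010 for the interferon response, 0.0029 for the TCA cycle and 0.031 for macrophage genes. Complex I (0.208) and the mitochondrial ribosome (0.173) were not called by fry. The Cyp2e1 call was lost without ERRKO_PBS replicate 1 or 3 or ERRKO_CL replicate 1 or 3, with adjusted p of 0.109, 0.085, 0.090 and 0.093.

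**Figure D3:**
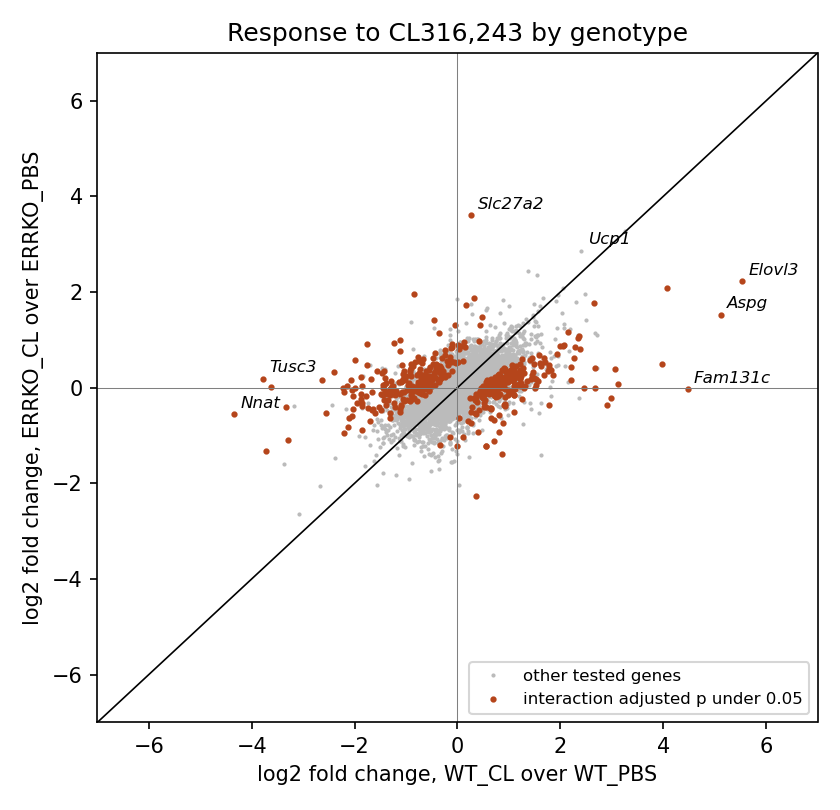
Log2 fold change for CL316,243 over PBS in WT (horizontal axis) and ERRKO (vertical axis) for 12249 genes, with the 474 genes past the interaction threshold in red and a diagonal line of equal response. Elovl3 lies at 5.54 in WT and 2.22 in ERRKO, and Slc27a2 at 0.27 and 3.61.

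The interaction asked whether the response to CL316,243 differed between genotypes, as the ERRKO response minus the WT response. Ucp1 did not differ detectably on the log2 scale (0.46 ± 0.43, adjusted p = 0.642) and nor did Dio2 (0.04 ± 0.51, adjusted p = 0.984), although both stayed lower in ERRKO with the agonist. The mean of Dio2 in ERRKO_PBS lay below the added 0.5, which understates its response in ERRKO. Its value therefore does not show equal fold responses in the genotypes. Cidea at 1.08 ± 0.33 did not pass (adjusted p = 0.098) but passed on the deposited scale (adjusted p = 0.041) and without ERRKO_PBS replicate 2 (1.36, adjusted p = 0.019). Responses smaller in ERRKO were those of Fam131c (-4.50 ± 0.29), Aspg (-3.59 ± 0.37), Fndc5 (-3.47 ± 0.59), Elovl3 (-3.31 ± 0.39) and Tesc (-3.26 ± 0.38). The opposite sign was found for Tusc3 (3.96 ± 0.16), Nnat (3.78 ± 0.24) and Akr1cl (3.62 ± 0.42), whose falls in WT were smaller or absent in ERRKO, for Gadd45b (2.92 ± 0.41) and for Slc27a2 (3.35 ± 0.29), which rose in ERRKO and was at 0.27 ± 0.20 in WT. Among 18 lipogenesis genes 2 passed, Elovl3 and Elovl6 (-2.46 ± 0.48, lost without WT_PBS replicate 2 at an adjusted p of 0.051), and 11 passed adjusted over the list alone, with a median of -1.35 and an adjusted p of 0.554 with an estimated correlation.

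In all 474 genes passed the interaction, 235 positive and 239 negative, against 629 on the deposited scale, 475 positive and 154 negative. Of the 474, 423 were also called in WT and 117 in ERRKO. They comprised 224 rises in WT that were smaller, absent or reversed in ERRKO and 197 falls in WT that were smaller, absent or reversed. In 2 genes the response had the same direction in both and was larger in ERRKO. A further 44 were called in ERRKO and not in WT, and 7 in neither. The 224 and 197 include 18 genes called in both genotypes in opposite directions. Of the genes called higher in WT with agonist, 603 were also called higher in ERRKO against 156 for independent lists, and of those lower 240 against 53.1. Across genes, which are not independent replicates, the responses correlated at r = 0.563. With edgeR's quasi-likelihood test on recovered reads the interaction was not called for Elovl3 (adjusted p = 0.235), Fam131c (0.056) or Akr1cl (0.128), which were near 0 in some groups. All 18 list calls were lost with an estimated correlation, and the count without single libraries ranged from 220 without WT_CL replicate 3 to 800 without WT_PBS replicate 3.

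**Figure D4:**
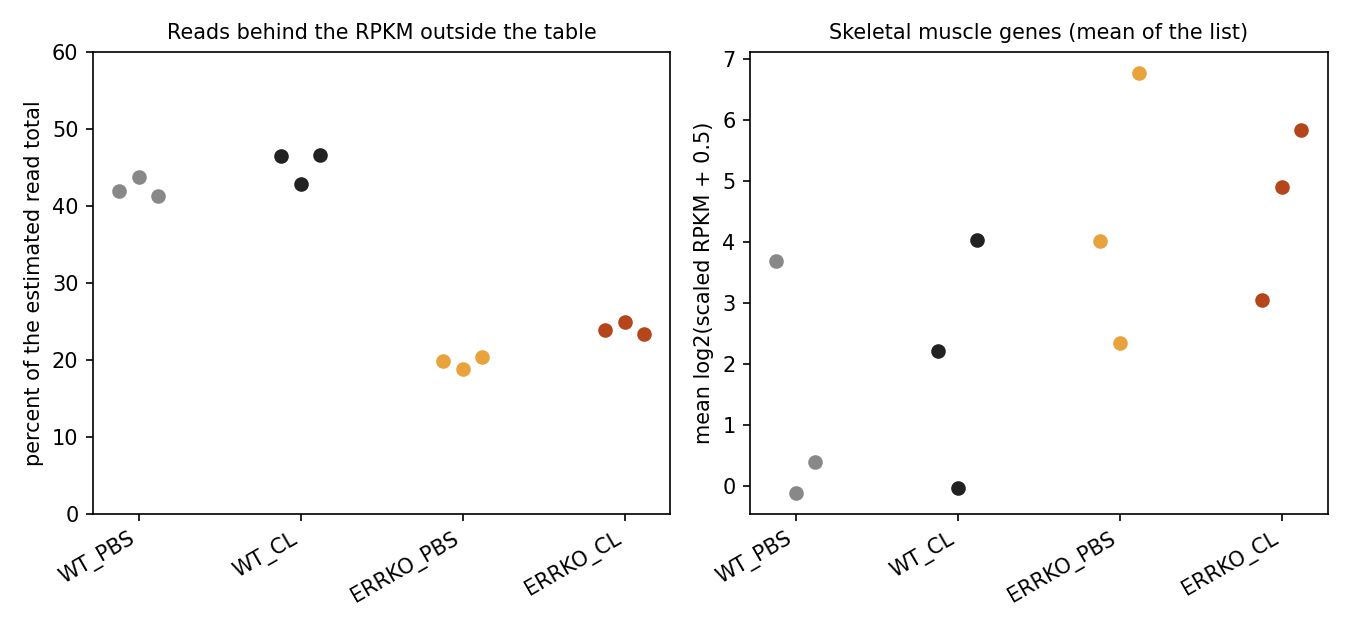
Percent of the estimated read total behind the RPKM that lies outside the genes of the second deposited table (left) and mean log2 of scaled RPKM plus 0.5 over 18 skeletal muscle genes (right), one point per library in the 4 groups. The share outside averages 42.3% in WT_PBS and 45.3% in WT_CL against 19.7% in ERRKO_PBS and 24.0% in ERRKO_CL, and the muscle level spreads widely within each group.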

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

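The tests of read totals, of muscle genes and of how alike the white adipocyte genes rose, and the comparison of the brown lineage medians with their spread, were chosen after the results were seen. The bound on the spread of the white adipocyte genes was then loosened, with its values known, to a multiple of the mean SE, and the PBS value exceeds only that later bound. Each count, gene and list in the next paragraphs drew attention because the response to CL316,243 differed between genotypes by the interaction test, on the median-ratio scale unless stated.

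The interaction called 629 genes on the deposited scale and 474 on the median-ratio scale. On the deposited scale 5 of 100 splits of the 12 libraries gave at least as many, with 6273 in the highest other split, so chance was not excluded there. On the median-ratio scale 2 of 100 did, a share under 0.05, with 1896 in the highest other split. Splits with several times the real count point to a structure of the samples. Effects of treatment or genotype carried by mixed splits would be such a structure, but what set those splits apart was not tested. The other splits are thus no clean reference, and the share does not exclude chance on this scale either. For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05, and 1 of 10, the real one, reached the real count in each. The real counts were 8877, 9451, 5553 and 2068 on the deposited scale with highest others of 0, 0, 0 and 1, and 4189, 5073, 3717 and 1293 on the median-ratio scale with highest others of 0, 0, 0 and 3, for ERRKO_PBS against WT_PBS, ERRKO_CL against WT_CL, WT_CL against WT_PBS and ERRKO_CL against ERRKO_PBS.

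Of the 10 largest interactions Tusc3 was at 3.96, Nnat at 3.78, Akr1cl at 3.62, Slc27a2 at 3.35, Gadd45b at 2.92, Fam131c at -4.50, Aspg at -3.59, Fndc5 at -3.47, Elovl3 at -3.31 and Tesc at -3.26. Among thermogenic and fatty acid genes Letmd1 was at -1.09, Pank1 at 1.56, Cpt1b at 0.88 and Acsl5 at -2.67, and the creatine transporter Slc6a8 at 1.31. Mitochondrial genes with smaller responses in ERRKO were Atp5g3 (-0.80), Dlst (-0.59), Mpc2 (-1.13), Pdhb (-1.24), Tfb2m (-0.68), Tfam (-0.61), Mrps27 (-1.07), Mrps5 (-0.63), Mrpl38 (-0.64), Dnaja3 (-0.71), Afg3l2 (-0.53) and Oma1 (-0.67). In lipid and sugar metabolism the interaction was -2.46 for Elovl6, 1.29 for Aqp7, -1.30 for Gk, -1.06 for Pfkp, -1.72 for Eno1, -0.92 for Hk2 and -1.13 for Ldha. For stress and sterol genes it was 1.25 for Pck2, 2.10 for Phgdh, -0.89 for Atf5, -1.02 for Nsdhl and -0.93 for Idi1. It was 1.01 for Inhbb, 2.81 for S100a8, -0.92 for Dhx58, -1.62 for Pbk, 2.78 for Nr4a1, 0.72 for Zfp36 and 1.45 for Jun. On the deposited scale the interaction calls of Tfam (adjusted p = 0.068), Afg3l2 (0.061), Oma1 (0.077), Gk (0.064), Hk2 (0.064) and Idi1 (0.057) were lost.

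The list interactions, as medians, were -0.31 for complex I, -0.36 for complexes II and III, -0.22 for ATP synthase, -0.30 for the TCA cycle, -0.14 for mitochondrial biogenesis, -0.27 for the mitochondrial ribosome, -0.15 for chaperones, -1.35 for lipogenesis, -0.36 for glycolysis and -0.33 for cholesterol synthesis. They were 0.18 for pan-adipocyte genes, 0.61 for white adipocyte genes, 0.29 for macrophage genes, -0.73 for lymphocyte genes, -0.55 for the interferon response, -0.38 for the cell cycle, 0.34 for extracellular matrix and 0.37 for immediate early genes. None of these 18 calls held with an estimated correlation, and fry called 2 lists. The call of the immediate early genes was lost on the deposited scale (adjusted p = 0.054).

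Reads outside the genes of the second deposited table made up 42.3 ± 1.28% of the estimated total in WT_PBS and 45.3 ± 2.10% in WT_CL, against 19.7 ± 0.747% in ERRKO_PBS and 24.0 ± 0.783% in ERRKO_CL (SD, n = 3). Reads of genes found only in the RPKM table count as outside here. A difference in total depth is argued against, since the mean totals differed by a ratio of 1.00. Reads of mitochondrially encoded transcripts, none of which are listed, are a candidate explanation that stays open: within groups the share outside and the level of 80 respiratory chain genes correlated at r = -0.287 (exact permutation p = 0.404 over 1296 permutations; rho = -0.357, exact p = 0.328) and at r = -0.155 without the 2 farthest libraries. Nuclear RNA stays open as well, since the median of 6 nuclear-retained RNAs was -0.38 under PBS and 0.20 under CL316,243. A change in the tissue brought by the deletion was not tested, and it cannot be told apart from these because the genotypes and the shares coincide.

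Skeletal muscle transcripts ranged from 0 to 389 scaled RPKM of Ckm and were highest in ERRKO_PBS replicate 3. Muscle taken with the tissue is a candidate explanation. The 18 muscle genes rose and fell together across libraries, with a median pairwise r of 0.959. Such an r does not show that the genes kept one ratio. Their log2 changes ranged from 0.80 to 4.45 in ERRKO_PBS against WT_PBS and from 0.29 to 3.86 in ERRKO_CL against WT_CL. The added 0.5 understates the change of low genes, so this range does not decide about one ratio either. Deletion of the receptors as the whole cause is argued against, since in 2 of 18 pairs of libraries of one treatment the ERRKO library lay below the WT library and the list differed by 3.80 (log2) between WT_PBS replicates 1 and 2. A partial contribution of the deletion to the level of muscle transcripts stays open.

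Of the 8 measured white adipocyte genes 7 were higher in ERRKO under PBS and 6 under CL316,243. Npr3 passed in neither (0.06 and 0.56, limma adjusted p = 0.90 and 0.13). Hoxc8 passed under PBS (1.03) but not under CL316,243 (0.45, adjusted p = 0.14). White fat taken with the tissue may contribute: the median of the brown lineage genes Zic1, Lhx8, Ebf2 and Prdm16 was 0.14 under PBS and -0.26 under CL316,243, above the bound of -0.5 set beforehand for excluding it. That bound left out the spread: the 4 genes had an SD of 0.185 under PBS and 0.587 under CL316,243. The median passes the bound by more than the SD under PBS but by less under CL316,243. Excluding white fat needed both treatments, so it is not excluded. The rises of the white genes were unequal, with an SD of 0.993 under PBS and 1.83 under CL316,243, against a mean SE of 0.247. This does not decide about a lower share of brown adipocytes. Equal rises would follow only for genes that brown adipocytes do not express, and their level in each cell type was not measured. An effect of the deletion on adipocytes stays open and untested.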

How the results depend on the processing

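The settings on the median-ratio scale, the muscle settings and the comparison of gene values between scales were chosen after the data were seen. For the deposited scale the main counts were 8877, 9451, 5553, 2068 and 629, and for the median-ratio scale 4189, 5073, 3717, 1293 and 474, in the order ERRKO_PBS against WT_PBS, ERRKO_CL against WT_CL, CL316,243 in WT, CL316,243 in ERRKO and interaction. For the genotype comparisons the deposited count fell with every rescaling: to 4574 and 5158 with quantile normalization, 4189 and 5073 with median-of-ratios scaling, 4293 and 5108 in the second deposited table and 4305 and 5083 in the count test. The construction of these settings, which remove the shift of the typical gene, shows the cause. The count test gave 3633 for CL316,243 in WT, 1218 in ERRKO and 412 for the interaction, and CL316,243 in ERRKO gave 1293 with median-of-ratios scaling and 1150 in the second table. Against the median-ratio counts, deposited scaling gave more than 1.5 times as many for the genotype comparisons and CL316,243 in ERRKO (8877, 9451 and 2068), and also more for CL316,243 in WT (5553) and the interaction (629). Library weights raised the interaction to 1424 on the deposited and 1124 on the median-ratio scale, and the cause was not tested.

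Without ERRKO_PBS replicate 3 and ERRKO_CL replicate 3 CL316,243 in ERRKO gave 881 and 472 and the interaction 335 and 207, with fewer samples. With the muscle transcript level as a covariate the median-ratio counts were 3147, 4346, 3590, 1242 and 442, and 627 of 651 gene values and 146 of 150 list values kept their direction and side of the threshold. Leaving out single libraries moved CL316,243 in ERRKO between 1018 (without ERRKO_CL replicate 2) and 2748 on the deposited scale and between 533 (without ERRKO_PBS replicate 1) and 1708 on the median-ratio scale. The deposited counts for CL316,243 in ERRKO were also lower without ERRKO_PBS replicate 1 (1022) or 3 (1323) or ERRKO_CL replicate 3 (1305), and those for the interaction without WT_PBS replicate 2 (343), WT_CL replicate 1 (399) or 2 (407), ERRKO_PBS replicate 1 (343) and ERRKO_CL replicates 1 (384), 2 (383) and 3 (406). The interaction moved between 296 (without WT_CL replicate 3) and 903, and between 220 (without WT_CL replicate 3) and 800 (without WT_PBS replicate 3). On the median-ratio scale CL316,243 in ERRKO also fell to 733, 662 and 760 without ERRKO_CL replicates 1, 2 and 3. The interaction fell to 245 without WT_PBS replicate 2, 283 without WT_CL replicate 1 or 2, 242 without ERRKO_PBS replicate 1, and 269, 236 and 290 without ERRKO_CL replicates 1, 2 and 3.

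The camera calls of 14, 17, 20, 15 and 17 lists on the deposited scale fell to 7, 8, 1, 4 and 0 with an estimated correlation, and those of 18, 18, 22, 17 and 18 on the median-ratio scale to 2, 3, 0, 1 and 0, while fry gave 2 for the interaction on either scale. The muscle list had medians of 3.72 under PBS and 3.47 under CL316,243 with deposited scaling, against 3.21 and 2.91 on the median-ratio scale, and its test direction turned, without passing.

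Some values changed sign. With quantile normalization CL316,243 in WT gave -0.00724 for Cox8a and -0.0194 for Atp5a1, and the cause was not tested. With deposited scaling ERRKO_PBS against WT_PBS gave 0.19 for Pcna, 0.00653 for Emcn, 0.14 for Esam, 0.0825 for Tie1 and 0.13 for Tek, and ERRKO_CL against WT_CL gave 0.15 for Atp2a2, 0.26 for Ifit2, 0.22 for Rsad2, 0.23 for Emcn, 0.22 for Egfl7 and 0.47 for Esam, where the shift of the typical gene that this scaling keeps shows the cause. Of 651 gene values 551 kept their direction and side of the threshold with deposited scaling, 627 in the count test, 610 with quantile normalization and 577 without the muscle-rich libraries. Of 150 list values 138 did with deposited scaling.

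A replicate block, with the replicate number as a term, gave 8832, 9455, 5288, 1790 and 477 genes on the deposited scale and 4046, 4929, 3527, 1101 and 365 on the median-ratio scale, and 13, 17, 21, 15 and 18, and 17, 18, 22, 17 and 18 lists. No pairing of samples by number was seen: correlations of same-numbered libraries ran from -0.22 to 0.37, and not every library matched its own number best. These values do not exclude a pairing. The interaction with only the groups compared was not run because it needs all groups. Depth limits genes near 0, where the count test lost the interaction of Elovl3, Fam131c and Akr1cl.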

Other observations

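Several gene groups outside the main account also moved. In WT, erythroid genes fell in 7 of 7 measured cases with CL316,243 (median -1.19, adjusted p = 0.349 with an estimated correlation), with the haemoglobin genes, whose near-identical copies share reads, and Alas2 at -1.24 ± 0.30. Immediate early genes fell in 7 of 12 (median -0.45, adjusted p = 0.286 with an estimated correlation), led by the nuclear receptor gene Nr4a1 (-2.63 ± 0.31). In ERRKO the agonist lowered 4 of 11 lymphocyte genes (median -0.75, adjusted p = 0.267 with an estimated correlation), including Lck (-0.99 ± 0.22), whose call was lost without ERRKO_PBS replicate 2 (adjusted p = 0.052) or ERRKO_CL replicate 1 (0.058). S100b, a gene of Schwann cells and also of brown adipocytes, was lower in ERRKO by -3.92 ± 0.32 under PBS and -3.89 ± 0.32 under CL316,243, the passing member of 7 nerve and Schwann cell genes in both. The interferon list, at 0.56 in ERRKO_PBS against WT_PBS, was at -0.01 in ERRKO_CL against WT_CL, where deposited scaling gave 0.50 with 10 genes higher.

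Other lists were not called between ERRKO_PBS and WT_PBS: camera gave adjusted p of 0.511 for futile creatine and calcium cycling (1 rose and 3 fell of 8), 0.553 for triglyceride genes (7 rose and 5 fell of 23), 0.212 for the integrated stress response (7 rose and 3 fell of 21), 0.487 for circadian clock genes (1 rose of 16) and 0.553 for lipogenesis (3 rose of 18). The creatine kinase gene Ckb fell (-1.98 ± 0.16) while the creatine synthesis gene Gamt rose (1.52 ± 0.22). Preadipocyte and fibroblast genes rose in 3 of 14 and fell in 1, with Gsn at 1.80 ± 0.18 (adjusted p = 0.311 with an estimated correlation, and the call was lost on the deposited scale at 0.303), and endothelial genes fell in 5 of 14, with Emcn at -0.57 ± 0.12 (adjusted p = 0.498 with an estimated correlation), a list call lost on the deposited scale (adjusted p = 0.090), where the list median (0.20) and Emcn changed sign. With deposited scaling triglyceride genes had 15 rises and 2 falls and the integrated stress response 16 rises. Futile cycling genes had 4 rises and 2 falls there, and circadian clock and lipogenesis genes 8 rises each. Preadipocyte and fibroblast genes had 12 rises and 1 fall, and endothelial genes 1 rise. The 2 measured genes of the ERR family are given with the genotype check, and 0 mitochondrially encoded genes were measured.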
